A study of Mus musculus with 8 samples.

How the data were processed

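The series measured how strongly mouse antibodies against UV lesions stained a DNA microarray of universal design, on which short sequences of every kind are printed in many contexts. An antibody against cyclobutane pyrimidine dimers (CPDs, dilution 1:400) and an antibody against 6-4 photoproducts (6-4PPs, dilution 1:80) were each applied, per the labels, to 2 UV-treated arrays and 2 arrays without UV. The 8 arrays thus form 4 groups of 2. The organism in the labels is the host of the antibodies. The UV dose, the staining protocol and the way the second DNA strand was made are not given in the sources used here.

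Each deposited file holds, per the file headers, Alexa 488 intensities of 180880 spots on a linear scale. The scanner intensity as deposited is a whole number with a ceiling of 65535 and was not background-subtracted. The deposited normalised intensity equalled it in every spot, because the columns for the Cy3 dye held only 1. The deposited adjusted intensity was the normalised intensity multiplied by a constant of the array and divided by the median of the local neighbourhood. The software behind these columns is not given in the sources used here. A printed sequence was given for 175866 spots, which hold 122095 different sequences of 60 bases, 111165 of them printed once. A shared 3′ end of 33 bases was present in 122086 sequences and absent from 9. The 5014 spots without a printed sequence (controls and unnamed spots) were left out of every comparison of sequences; the unnamed spots served only to check for a rise of the array surface. No spot carried a quality flag (0 flagged spots).

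Values were the log2 of the adjusted intensity, averaged over the spots of one sequence and centred on the median of the array. For each of 2080 6-mers, with reverse complements merged, the value on an array was the median over the probes that hold the 6-mer in either orientation (153 to 122093 probes, median 550). The same was done for 136 merged tetranucleotides. The 16 6-mers found on over 90 percent of the sequences lie in the shared 3′ end and sit at the array median by construction. They hold no dipyrimidine step, so the list of 6-mers without a step includes them. UV and non-UV arrays were compared for each antibody, and the difference of the UV effects between the antibodies was tested as an interaction, with limma 3.58.1 (lmFit and eBayes) in 1 fit over all 8 arrays. P-values were adjusted with the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. A least-squares regression per array of centred log2 signal on the numbers of TT, TC, CT and CC steps, summed over both strands, gave 1 coefficient per step type, and the coefficients were compared with limma.

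The 12 lists of 6-mers were 6-mers without a dipyrimidine step, 6-mers with 1 step only (TT, TC, CT or CC), all-pyrimidine tracts, T tracts (TTTT), C tracts (CCCC), 6-mers with TCG or CCG, with TTC, with TTA, and 12 core sequences of DNA-binding factors. Each was counted, adjusted over all 6-mers and over the list alone, and tested with limma camera at a preset correlation of 0.01. Array medians were compared with an exact two-sided permutation test, which cannot go below p = 0.333 with 2 arrays against 2. Sequences are named by a rule: per antibody, the 12 largest rises and 8 largest falls past the threshold whose UV arrays both lie on 1 side of both non-UV arrays; for the difference, the 10 largest each way; all 4 step types; the 5 highest and 5 lowest tetranucleotides with a central dipyrimidine; and the 12 factor cores. The groups, tests, lists and naming rule were fixed before the data were examined. The alternatives tried were the unadjusted intensity column, no centring, quantile normalization, an offset of 100 on the log scale, saturated spots left out, the dimmest 25 percent of probes left out, 5-mers and 7-mers, means for medians, the printed strand alone, arrays of 1 antibody alone, eBayes with trend and robust, a replicate block, each array left out in turn, a linear scale, a G and C term, separate strand terms, and an estimated correlation in camera.

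Probes with a single isolated dipyrimidine step, or a single pyrimidine run, were compared with the 550 probes without any step. This comparison was chosen after the data had been seen. A class needed at least 10 probes. For each array, the median log2 signal of a class was set against that of the probes without a step, and class values above that level are given in intensity units.

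The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. The CPD comparison of 6-mers and probes and the step regression were tested on simulated data; the other fits were not. For the CPD comparison over 2080 6-mers, 84 percent of simulated log2 changes of 0.1 were recovered, and 100 percent of those of 0.2, 0.5 and 1. There were 35 false calls, beside 42 of 50 changed 6-mers recovered at 0.1 and 50 of 50 at each larger change. This share of false calls exceeds what the threshold on adjusted p allows, so adjusted p-values of 6-mers can be too small. Over 122095 probes of the CPD comparison, 18 percent of simulated log2 changes of 1 were recovered and 100 percent of those of 2, 3 and 4, with 1 false call. The step regression returned simulated coefficients over 122095 probes with a largest error of 0.00618. For arrays, the number of arrays limits the precision: p-values rest on 2 arrays per group. The labels do not say whether replicates came from separate preparations, so p-values measure only the spread between these arrays, which may be technical.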

Results

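Antibody staining of a universal DNA array was measured with and without UV treatment, for an antibody against cyclobutane pyrimidine dimers (CPDs) and an antibody against 6-4 photoproducts (6-4PPs). Both are lesions in which UV light joins adjacent pyrimidines of 1 strand, so a sequence needs a TT, TC, CT or CC step (a dipyrimidine step) to carry them. The 8 arrays form 4 groups of 2, and each array holds 122095 different 60-base sequences with a median of 5 dipyrimidine steps, counted on both strands. All 32896 merged 8-mers are printed. The design text states the purpose as measuring antibody signal for short sequences. Saturated spots numbered 89 to 288 per array.

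UV treatment raised the staining of both antibodies. With the CPD antibody the median adjusted intensity was 2789 ± 148 (SD, n = 2) on UV arrays and 1135 ± 134 on non-UV arrays, a 2.46-fold rise (log2 1.30). With the 6-4PP antibody the medians were 5628 ± 17.0 and 1368 ± 202, a 4.14-fold rise (log2 2.05). Both UV arrays lay above both non-UV arrays for each antibody. The exact two-sided permutation test gave p = 0.333 for each antibody (n = 2 per group), which is the smallest p this design allows. These values include the unsubtracted background, so the folds understate the rise of lesion signal.

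Staining grew with the number of dipyrimidine steps on UV arrays and not on non-UV arrays. From probes with 0 steps to probes with 12 steps, CPD signal after UV went from 1610 ± 10.2 to 7133 ± 535 (SD, n = 2), 4.43 times the level. 6-4PP signal after UV went from 1953 ± 2.05 to 12887 ± 292, 6.60 times the level. Only 69 probes have 12 steps. From 8 to 11 steps the signal was nearly level, between 5900 and 6131 with CPD and between 11453 and 12200 with 6-4PP. Without UV the group means at 0 to 12 steps lay between 1128 and 1149 with the CPD antibody and between 1352 and 1402 with the 6-4PP antibody. Replicate arrays correlated across 6-mers with Pearson r = 0.999 (CPD) and 0.998 (6-4PP) after UV, and with 0.235 and 0.447 without UV. Across probes r was 0.944 and 0.948 after UV and near 0 without it (-0.00165 and 0.0109). These are correlations across sequences, which are not independent replicates.

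**Figure D1:**
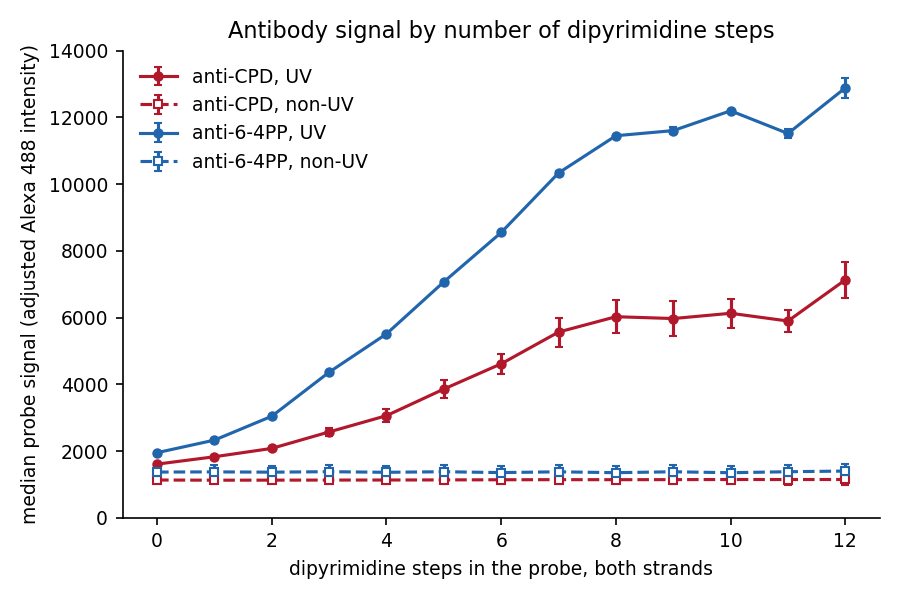
Median adjusted intensity of probes against their number of dipyrimidine steps, with the mean and SD of 2 arrays per group. UV arrays climb from 1610 to 7133 (CPD) and from 1953 to 12887 (6-4PP), while non-UV arrays stay level.

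With the CPD antibody, the 12 6-mers that UV treatment raised most all hold TT on one strand. TAATTA, the core bound by many homeodomain proteins, rose most, by 2.09 log2 units relative to the array median (SE 0.020, n = 2 per group) and 13.4-fold before centring. The TT step carried nearly the whole step effect: each added TT raised CPD signal by 0.66 log2 units (SE 0.0094, 1.58-fold). GGCGCC was lowest, at -0.92 relative to the array median. Before centring every 6-mer rose with UV, by 0.73 to 3.74 log2 units with a median of 1.49, so a fall here means a smaller rise than the typical probe.

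The 12 6-mers with the largest CPD rise relative to the array median were TAATTA (2.09), AATTAA (2.09), AATTAC (2.08), ATTGCG (2.05), CAATTA (2.03), AAATTA (2.02), AAAATT (1.98), AATTAG (1.95), AATTAT (1.95), AATAAT (1.93), AATTTA (1.93) and AAATTT (1.92). Of these 12, 9 hold TTA and 0 hold TC. Before centring they rose 11.9-fold to 13.4-fold. The 8 with the largest fall were GGCGCC (-0.92), CACGTG (-0.90), CCCACG (-0.90), GACGTC (-0.88), CGTGCC (-0.88), GACACC (-0.88), CGTACG (-0.88) and ACGCCC (-0.88). Of these, 0 hold TT, 2 hold TC and 2 have no dipyrimidine step, and before centring they rose 1.66-fold to 1.71-fold. The largest SE among the named 6-mers was 0.0428 and the largest limma adjusted p for CPD was 8.33e-07.

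By step type, the CPD regression gave 0.016 (SE 0.0048, limma adjusted p = 0.0105) for TC, 0.033 (SE 0.0046, adjusted p = 0.000158) for CT and -0.030 (SE 0.0050, adjusted p = 0.000437) for CC, beside an adjusted p of 4.25e-12 for TT. The 3 small coefficients each changed sign under at least 1 other setting, among them -0.07 for TC and -0.019 for CT with the dimmest probes left out, and 0.0060 for CC with G and C content in the model. TT on the printed strand gave 0.95 per step and TT on the complement strand 0.38. The 4 step counts accounted for 53.2% ± 1.49 (SD, n = 2) of the probe variance after UV and 0.143% ± 0.184 without UV.

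Among tetranucleotides with a central dipyrimidine, all 16 with a central TT rose with the CPD antibody relative to the array median. ATTA (1.55), ATTT (1.47), ATTG (1.43), TTTT (1.28) and TTTA (1.28) were highest. Of the 16 with a central TC, 5 rose and 11 fell. Of the 16 with CT, 6 rose, 9 fell and 1 did not pass the test, and for CC these numbers were 1, 14 and 1. CCCG (-0.61), CCTG (-0.60), GCCC (-0.60), CCTC (-0.59) and GCTG (-0.58) were lowest, although before centring these 5 rose by 1.04 to 1.07. The largest limma adjusted p among the named tetranucleotides of both antibodies was 2.64e-05.

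With the CPD antibody, 5 of the 12 lists of 6-mers were called as raised. Of 80 6-mers whose only step is TT, 78 rose and 2 fell relative to the array median (limma camera adjusted p = 3.05e-13; adjusted p = 0.258 with an estimated correlation). All 40 T tracts rose (camera adjusted p = 7.35e-10; adjusted p = 0.448 with an estimated correlation), as did all 233 6-mers with TTA (1.29e-30; adjusted p = 0.237 with an estimated correlation). For TTC, 247 of 255 rose, 4 fell and 4 did not pass (5.44e-23; adjusted p = 0.237 with an estimated correlation). Of 64 all-pyrimidine tracts 43 rose and 21 fell (0.00798; adjusted p = 0.450 with an estimated correlation), and this camera call was not kept without centring (adjusted p = 0.0933).

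The other CPD lists lay below the array median, although each of their medians rose before centring. The list without a dipyrimidine step includes the 16 6-mers of the shared 3′ end, which sit at the array median by construction. Of 80 6-mers with 1 TC step, 76 fell, 3 rose and 1 did not pass (camera adjusted p = 2.18e-09; adjusted p = 0.448 with an estimated correlation). With 1 CT step 69 of 80 fell, 5 rose and 6 did not pass (2.25e-07; adjusted p = 0.448 with an estimated correlation). With 1 CC step 79 fell and 1 rose (1.85e-10; adjusted p = 0.448 with an estimated correlation). Of 40 C tracts 36 fell and 4 rose (1.01e-04; adjusted p = 0.450 with an estimated correlation). Of 414 6-mers with TCG or CCG, in which a dipyrimidine adjoins a CpG, 304 fell, 106 rose and 4 did not pass (1.62e-06; adjusted p = 0.450 with an estimated correlation). Of 72 6-mers without a dipyrimidine step 47 fell, 10 rose and 15 did not pass (9.29e-04; adjusted p = 0.450 with an estimated correlation). The counts adjusted over the list alone were the same for all 12 lists.

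The 12 factor cores went both ways with the CPD antibody relative to the array median, 5 up and 7 down (camera adjusted p = 0.725; list median -0.28, list mean 0.15, camera pointing down). The TATA box TATAAA (1.32), the GATA core AGATAA (1.09), the telomere repeat TTAGGG (0.93), the ETS core TTCCGG (0.11) and TAATTA (2.09) rose. The GC box GGGCGG (-0.83), the p53 core CATGTC (-0.65), the cAMP response element core TGACGT (-0.49), the AP-1 core TGACTC (-0.36), the RUNX core TGTGGT (-0.29), the NF-κB core GGGACT (-0.26) and the E-box CACGTG (-0.90) fell. The largest SE among the cores was 0.035. The sign of TTCCGG turned with quantile normalization (-0.09), with dim probes left out (-0.30) and on the printed strand alone (-0.34). With means for medians TGACTC turned to 0.030, and TGTGGT (-0.016) and GGGACT (-0.029) were no longer past the threshold. With dim probes left out TGTGGT turned to 0.10 (adjusted p = 5.82e-04) and TGACGT to 0.0011.

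The CPD comparison put 2042 6-mers past the threshold, 947 higher and 1095 lower than the array median, while without centring all tested 6-mers were higher and 0 lower. It also called 97271 of 122095 probes (48209 higher, 49062 lower; 112361 higher and 2 lower without centring) and 123 tetranucleotides (50 higher, 73 lower; all higher and 0 lower without centring). With quantile normalization, 8435 probes were called.

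With the 6-4PP antibody, the 12 6-mers that UV treatment raised most all hold TT, and 7 of them also hold TC. ATTAAT rose most, by 1.69 log2 units relative to the array median and 15.6-fold before centring. In the regression each added TC raised 6-4PP signal by 0.46 (SE 0.0048, 1.38-fold) and each added TT by 0.35 (SE 0.0094, 1.27-fold). Isolated steps, described below, gave the other order. Relative to probes without a step, the 6-4PP effect on the printed strand was 1.95 for TT and 1.20 for TC. ACACGT was lowest (-1.30). Before centring every 6-mer rose, by 0.98 to 3.97 log2 units with a median of 2.46.

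The 12 6-mers with the largest 6-4PP rise relative to the array median were ATTAAT (1.69), TAATGA (1.61), ATTAAG (1.58), GATTAA (1.57), CTTAAG (1.51), GATCAA (1.498), AATCAA (1.497), AATTAA (1.45), TAATCA (1.44), CATTAA (1.44), GATTGA (1.44) and GATTAC (1.41). Of these 12, 9 hold TTA, and before centring they rose 12.95-fold to 15.6-fold. The 8 with the largest fall were ACACGT (-1.30), ACGCGT (-1.29), ACATGT (-1.22), AACGTA (-1.21), GACGTA (-1.13), ACGTAT (-1.10), ACGTAC (-1.08) and ACCGTA (-1.08). Of these, 5 have no dipyrimidine step, and before centring all 8 rose, 1.97-fold to 2.30-fold. The largest limma adjusted p for these 20 was 6.71e-08.

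The other 2 step types had smaller 6-4PP coefficients, 0.13 (SE 0.0046, limma adjusted p = 3.35e-09) for CT and 0.053 (SE 0.0050, adjusted p = 5.15e-06) for CC. TC on the printed strand gave 0.57 per step and on the complement strand 0.36, and TT gave 0.50 and 0.21. For CC the complement strand alone gave 0.0023 (adjusted p = 0.605). The step counts accounted for 34.4% ± 0.738 (SD, n = 2) of the probe variance after UV and 0.0159% ± 9.89e-04 without UV.

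**Figure D2:**
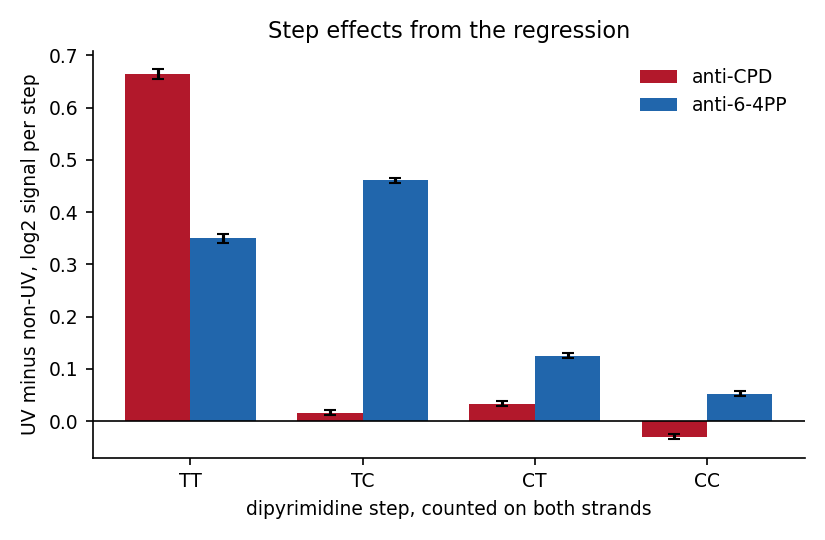
Log2 change of signal per dipyrimidine step from the regression on each array, by step type and antibody, from 2 arrays per group. TT reaches 0.66 with the CPD antibody, and TC and TT reach 0.46 and 0.35 with the 6-4PP antibody. Isolated steps give the other order of TC and TT with 6-4PP. Coefficients of non-UV arrays lie near 0.

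Central TT and central TC tetranucleotides stood alike in number with the 6-4PP antibody: in each class 12 of 16 rose and 4 fell relative to the array median. With a central CT 10 rose, 5 fell and 1 did not pass, and with CC 6 rose and 10 fell. ATTA (1.18), CTTA (0.99), ATCA (0.87), ATTG (0.84) and ATTC (0.79) were highest. ACCG (-0.44), GTTT (-0.43), GCTG (-0.40), ACCC (-0.36) and ACTG (-0.35) were lowest, although before centring they rose by 1.84 to 1.93.

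Lists of 6-mers rich in TTA, TTC or pyrimidine tracts rose with the 6-4PP antibody. Of 233 6-mers with TTA, 190 rose, 36 fell and 7 did not pass (limma camera adjusted p = 6.26e-08; adjusted p = 0.449 with an estimated correlation). For TTC 201 of 255 rose, 49 fell and 5 did not pass (1.17e-05; adjusted p = 0.449 with an estimated correlation), and 61 of 64 all-pyrimidine tracts rose and 3 fell (1.40e-05; adjusted p = 0.449 with an estimated correlation). The T tracts, with 28 of 40 up, 9 down and 3 not past, were not called by camera (adjusted p = 0.408). Neither were 6-mers with 1 TT step, 44 up, 35 down and 1 not past (0.702), those with 1 TC step, 38 up, 38 down and 4 not past (0.302), or those with TCG or CCG, 227 up, 176 down and 11 not past (0.472). For these 3 lists camera pointed down, while the list medians were 0.22, 0.01 and 0.12 and the means 0.12, -0.03 and 0.03.

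Below the array median with the 6-4PP antibody were 78 of 80 6-mers with 1 CC step, with 2 above it (camera adjusted p = 1.05e-15; adjusted p = 0.449 with an estimated correlation). With 1 CT step 72 fell and 8 rose (6.99e-13; adjusted p = 0.449 with an estimated correlation). Without any step 47 of 72 fell, 8 rose and 17 did not pass (9.99e-07; adjusted p = 0.449 with an estimated correlation). Of 40 C tracts 27 fell, 11 rose and 2 did not pass (0.00535; adjusted p = 0.904 with an estimated correlation). Before centring the median of each of these lists rose. The list without any step again includes the 16 6-mers of the shared 3′ end, fixed at the array median. The counts adjusted over the list alone were the same for all 12 lists.

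The factor cores again went both ways with the 6-4PP antibody, 5 up, 6 down and 1 not past (camera adjusted p = 0.559; list median -0.03, list mean 0.03, camera pointing down). TAATTA (1.30), TTAGGG (0.85), AGATAA (0.76), the AP-1 core TGACTC (0.57) and the NF-κB core GGGACT (0.23) rose relative to the array median. CACGTG (-0.96), TGACGT (-0.74), the RUNX core TGTGGT (-0.58), GGGCGG (-0.48), CATGTC (-0.47) and TTCCGG (-0.12) fell. TATAAA stood at 0.06 (limma adjusted p = 0.111), at 0.11 (adjusted p = 0.00390) without 6-4PP UV array 1, and fell with dim probes left out (-0.32), on the printed strand alone (-0.21) and with means for medians (-0.056). On the printed strand alone GGGACT changed sign (-0.12) and AGATAA was not past the threshold (0.021).

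For 6-4PP, 2003 6-mers were past the threshold, 1169 higher and 834 lower than the array median, against all higher and 0 lower without centring. The comparison called 93235 probes (44459 higher, 48776 lower; 117167 higher and 2 lower without centring) and 124 tetranucleotides (71 higher, 53 lower; all higher and 0 lower without centring). The number of probes called was 6561 with quantile normalization, and 59547 of 91571 with the dimmest 25 percent of probes left out.

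The antibodies differed in all 4 step types. The TC step added 0.45 log2 units less with the CPD antibody than with the 6-4PP antibody (difference -0.45, SE 0.0067, limma adjusted p = 7.57e-12). The TT step added 0.31 more (SE 0.013, adjusted p = 1.57e-08). Differences were smaller for CT (-0.09, SE 0.0065, adjusted p = 6.40e-07) and CC (-0.08, SE 0.0071, adjusted p = 2.35e-06).

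The 10 6-mers whose UV effect was larger with CPD were AAAAAC (1.96), AAAACC (1.79), GTTAAC (1.78), GTTATA (1.74), GTAAAC (1.71), AAAACG (1.70), AAATTT (1.69), AACGTT (1.68), GTTACA (1.66) and GGTTAC (1.62). All 10 hold TT, 9 hold GTT on one strand and 0 hold TC. The 10 whose UV effect was larger with 6-4PP were GATCAC (-1.75), GGATCC (-1.74), GATCGA (-1.70), CGATCG (-1.69), CTGATC (-1.68), CCGATC (-1.67), GGATCA (-1.62), GAGCTC (-1.61), ATCATC (-1.60) and CTCATC (-1.60). All 10 hold TC, 9 hold ATC and 0 hold TT. The largest limma adjusted p among the 20 was 2.20e-07, and none of the 20 changed sign without centring.

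**Figure D3:**
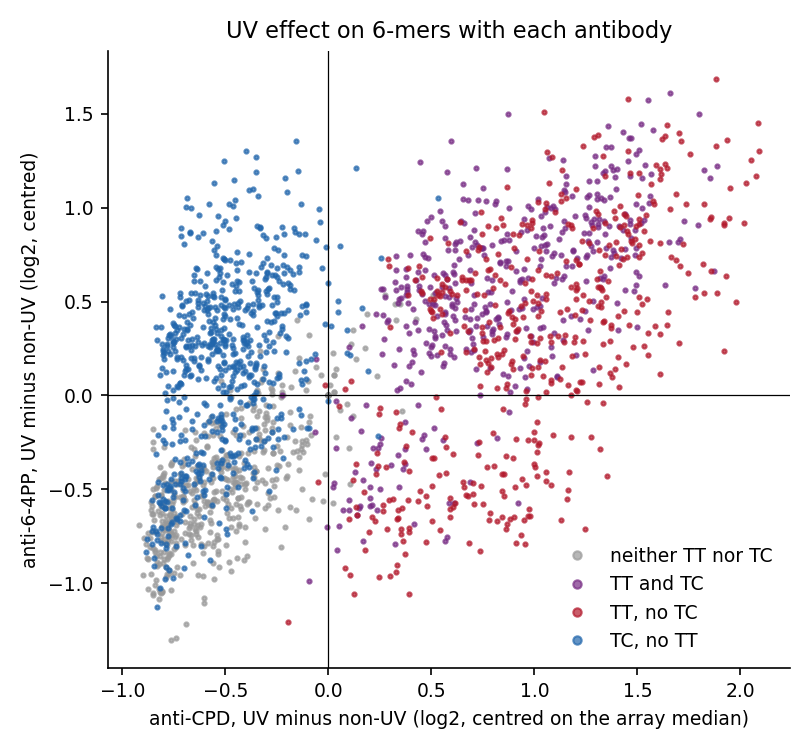
UV effect on all tested 6-mers relative to the array median (log2), 6-4PP antibody against CPD antibody, coloured by the steps a 6-mer holds. The effects of the antibodies correlate with Pearson r = 0.582.

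Across the 6-mers the UV effects of the antibodies correlated with Pearson r = 0.582 and Spearman rho = 0.589, a relation across sequences. Relative to the array medians, signal of both antibodies rose on 733 6-mers, where independent lists would share 532, and both fell on 635, where independent lists would share 439. For 422 6-mers the CPD effect was a fall and the 6-4PP effect a rise, for 191 the reverse, and 99 did not pass with one or both. Of the 12 named CPD rises, 12 were past the threshold for the difference, all toward CPD. Of the 12 named 6-4PP rises, 9 were past it, 5 toward CPD and 4 toward 6-4PP. Without centring, 4 of the named CPD rises were past it, all toward CPD, and the difference of 1 of the 12 changed sign. Of the named 6-4PP rises 9 were then past it, 0 toward CPD and 9 toward 6-4PP, and 6 of the 12 changed sign.

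By list, all 80 6-mers with 1 TT step (limma camera adjusted p = 2.07e-17; adjusted p = 0.438 with an estimated correlation) and all 40 T tracts (9.60e-12; adjusted p = 0.438 with an estimated correlation) leaned to CPD, with list medians of 0.76 and 1.17 (0.13 and 0.54 without centring). Of 233 6-mers with TTA 204 leaned to CPD and 16 to 6-4PP, and 13 did not pass (1.31e-18; adjusted p = 0.438 with an estimated correlation). For TTC these numbers were 191, 46 and 18 (2.65e-09; adjusted p = 0.438 with an estimated correlation). With 1 CT step they were 45, 17 and 18 (0.0301; adjusted p = 0.847 with an estimated correlation; 0.404 without centring). Without centring the medians of these 3 lists turned to -0.07, -0.26 and -0.51. To 6-4PP leaned 63 of 80 with 1 TC step, with 6 toward CPD and 11 not past (1.33e-08; adjusted p = 0.621 with an estimated correlation). So did 260 of 414 with TCG or CCG, with 105 toward CPD and 49 not past (3.15e-06; adjusted p = 0.800 with an estimated correlation), and 31 of 40 C tracts, with 3 toward CPD and 6 not past (8.67e-04; adjusted p = 0.800 with an estimated correlation).

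Camera did not call the remaining lists for the difference. These were 6-mers without a step (24 toward CPD, 13 toward 6-4PP, 35 not past; adjusted p = 0.395), with 1 CC step (30, 29 and 21; 0.912), all-pyrimidine tracts (26, 34 and 4; 0.630) and factor cores (7, 4 and 1; 0.455). For 1 CC step the median was -0.0023 and the mean 0.02, with camera pointing up. The list without a step includes the 16 6-mers of the shared 3′ end, fixed at the array median with both antibodies. Adjusted over the list alone, the counts toward CPD and 6-4PP were 23 and 11 without a step, 30 and 26 with 1 CC step and 205 and 16 with TTA, and the same as over all 6-mers for the other 9 lists.

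Among the cores, TATAAA (1.26) and TAATTA (0.79) leaned to CPD, and TGACTC (-0.93), GGGACT (-0.50), GGGCGG (-0.35) and CATGTC (-0.18) leaned to 6-4PP, although CATGTC turned to 0.14 and GGGCGG was not past the threshold (-0.021) with means for medians. Without centring TAATTA was not past it either (0.16, limma adjusted p = 0.488). AGATAA (0.34), TGTGGT (0.29), TGACGT (0.25), TTCCGG (0.23) and TTAGGG (0.07) leaned to CPD relative to the array medians and turned to -0.29, -0.34, -0.38, -0.40 and -0.56 without centring. The E-box CACGTG did not pass (0.06, limma adjusted p = 0.292), but passed at 0.12 without CPD UV array 1 (adjusted p = 0.00212), at 0.22 with means for medians (adjusted p = 1.35e-06), at -0.57 without centring (adjusted p = 0.00879) and at -0.17 with dim probes left out (adjusted p = 0.00243).

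For the difference, 1817 6-mers were past the threshold, 898 toward CPD and 919 toward 6-4PP, against 133 and 1350 without centring, where the larger overall rise of 6-4PP staining enters. Of the tetranucleotides 115 were past it (47 and 68; 3 and 102 without centring). Of 122095 probes 63111 were past it, 40990 toward CPD and 22121 toward 6-4PP, against 8028 and 34026 of 42054 without centring. Same-numbered arrays of both antibodies deviated together within a UV condition, and with these pairs as a random block 76854 probes were past it, 50389 toward CPD and 26465 toward 6-4PP. With quantile normalization limma called 0 probes, with 15640 at an unadjusted p under 0.05. The antibodies were used at different dilutions, so their intensities have no common scale. Log2 differences between the antibodies, also those of isolated steps, runs and triplets below, depend on the signal over background of each antibody.

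Probes with a single dipyrimidine step isolate the signal of 1 step in known flanking bases, and were chosen for description after the data had been seen. A lone TT on the printed strand gave 6991 ± 623 intensity units (SD, n = 2) above the level of probes without a step with the CPD antibody after UV, and 5695 ± 307 with the 6-4PP antibody. A lone TC gave 168 ± 20.7 and 2600.4 ± 12.3, which is 2.40% of the TT signal with CPD and 45.7% with 6-4PP. A lone CT gave 335 ± 34.1 and 488 ± 46.02 (4.79% and 8.58%), and a lone CC gave 65.1 ± 5.02 and 178 ± 4.02 (0.931% and 3.13%). Log2 values of these classes include the unsubtracted background, so differences between antibodies depend in part on the signal over background of each. Tested on the log2 scale, the difference between antibodies was 0.47 for TT (limma adjusted p = 0.00131) and -1.06 for TC (adjusted p = 3.53e-08). It was not past the threshold for CT (-0.03, adjusted p = 0.325) or CC (-0.05, adjusted p = 0.0624). Without 6-4PP non-UV array 1 the CC difference was -0.067. CT on the complement strand passed at 0.06 (limma adjusted p = 0.0146). That call was not kept with the unadjusted intensity column (0.032, limma adjusted p = 0.237). It was also lost when any 1 of the CPD arrays was left out (0.058 to 0.063). On the complement strand a lone TT gave 1608 ± 272 and 1169 ± 47.4, and the printed strand gave 4.35 and 4.87 times as much. For TC the printed strand gave 2.70 and 2.54 times as much.

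At TT, TC and CT steps the base before the step changed 6-4PP signal more than CPD signal. With the 6-4PP antibody ATTA gave 12065 ± 298 (SD, n = 2) and GTTA 484 ± 12.8, a ratio of 24.9, while with the CPD antibody they gave 10707 ± 808 and 4974 ± 401, a ratio of 2.15. Before a G the ratio of ATTG to GTTG was 22.3 with 6-4PP and 4.03 with CPD. For TC the 6-4PP ratio of ATCA to GTCA was 15.2, from 5519 ± 173 and 364 ± 20.9, and the CPD ratio 3.08. ATCG, a TC step within a CpG context, gave 3543 ± 4.40 with 6-4PP and 168 ± 25.5 with CPD. GTCG gave 266 ± 32.7 and 21.8 ± 28.6, so the ratios of ATCG to GTCG were 13.3 and 7.70. The CPD ratio rests on a GTCG value smaller than its SD. On the log2 scale the gain from A over G was smaller with CPD than with 6-4PP for ATTA and GTTA (difference -1.60, limma adjusted p = 2.33e-10), for ATTG and GTTG (-0.53, adjusted p = 5.30e-06) and for ATCA and GTCA (-1.47, adjusted p = 8.95e-09). These log2 values include the background, 1610 for CPD at probes without a step. Above it CPD gave only 332 for ATCA and 108 for GTCA, and 799 for ACTA and 297 for GCTA. The CPD gain at TC, CT and CC steps is thus pressed toward 0, which can make up part of the differences there. Above background the ratio of ACTA to GCTA was 8.09 with 6-4PP and 2.69 with CPD. For CT steps the log2 difference was -0.21 before A (adjusted p = 0.00403) and -0.14 before G (adjusted p = 0.00188). For CC steps it was not past the threshold, before A (-0.07, adjusted p = 0.147) or before G (-0.04, adjusted p = 0.174), although before A it passed without 6-4PP non-UV array 1 (-0.11, adjusted p = 0.0129).

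**Figure D4:**
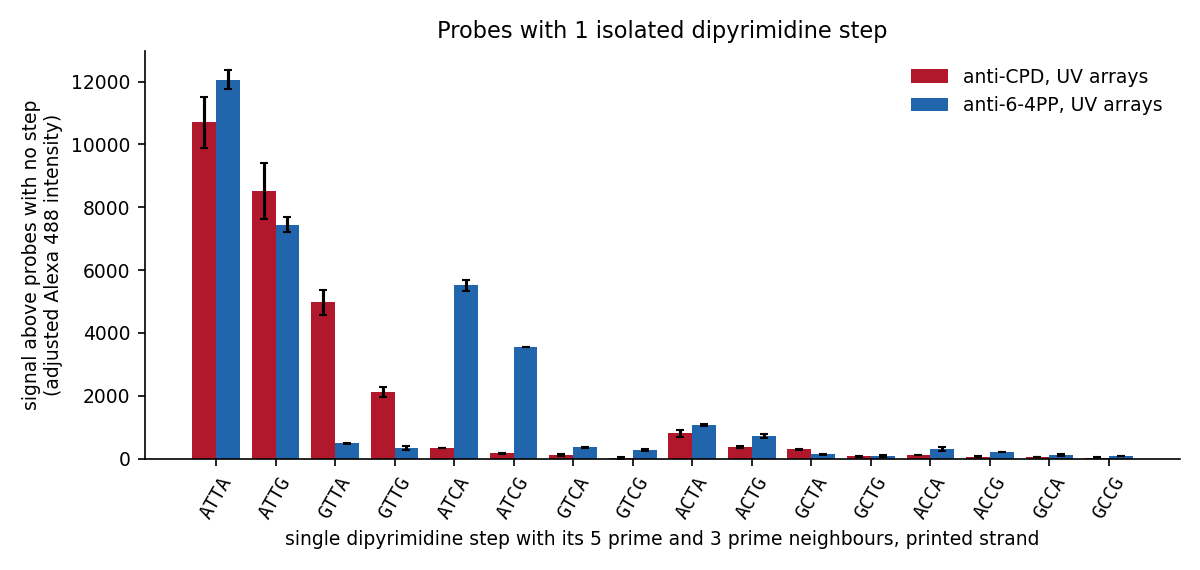
Signal of a single printed-strand step above probes without a step (intensity units) by step and flanking bases after UV, with the mean and SD of 2 arrays per antibody. With 6-4PP, ATTA reaches 12065 and GTTA 484, and with CPD they reach 10707 and 4974.

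Longer runs of T on the printed strand separated the antibodies further. A lone run of 6 T on the printed strand gave 12246 ± 1466 (SD, n = 2) above probes without a step with the CPD antibody, against 6991 ± 623 for TT. With the 6-4PP antibody the run of 6 T gave 4129 ± 705, against 5695 ± 307 for TT and 3407 ± 68.0 for TTT. The difference between antibodies was 0.47 log2 units for TT, 1.05 for TTT, 1.18 for TTTT, 1.48 for TTTTT and 1.49 for the run of 6, with limma adjusted p from 5.27e-06 (TT) to 8.42e-19 (TTTTT). The runs were fitted apart from the steps, with the same SE of 0.0896 for every run, and p for TT therefore differs from the 0.00131 given above. This fit pools the spread over all runs as if they were independent. They were read on the same arrays, so these p-values can be far too small. Only 13 probes stand behind the run of 6. On the complement strand the difference was 0.33 for TT, 0.64 for TTT, 0.84 for TTTT, 0.87 for TTTTT and 0.85 for the run of 6, and the 6-4PP signal of the run of 6 (1136 ± 89.8) lay near that of TT (1169 ± 47.4).

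**Figure D5:**
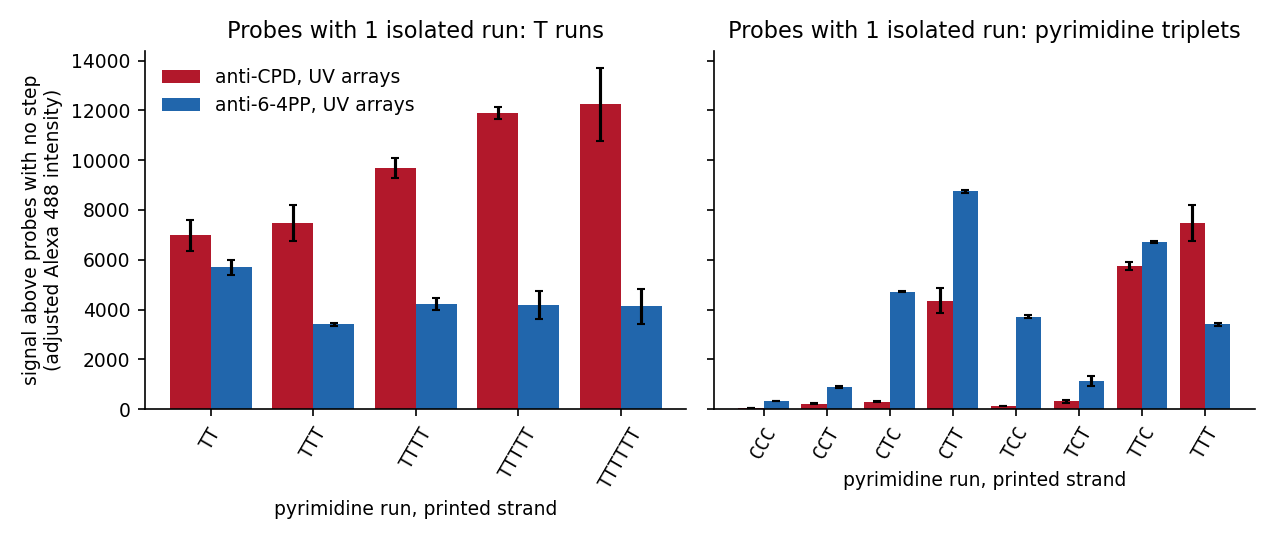
Signal of a single printed-strand run of T above probes without a step (intensity units) against the length of the run after UV, with the mean and SD of 2 arrays per antibody. CPD signal goes from 6991 at TT to 12246 at 6 T, and 6-4PP signal from 5695 to 4129.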

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

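The tests of the 3 patterns weighed here, and the comparison of isolated steps, were chosen only after the results had been seen; the differences between antibodies in steps, 6-mers, tetranucleotides, probes and lists were planned before the data were examined.

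The UV effect differed between the antibodies by the interaction test for all 4 step types, with CPD minus 6-4PP effects per step of 0.31 for TT, -0.45 for TC, -0.092 for CT and -0.083 for CC. Isolated steps pooled over both strands, however, gave no difference past the threshold for CT (0.037) or CC (-0.038), and on the complement strand CT passed the other way (0.060). This last call was not kept with the unadjusted intensity column (0.032, limma adjusted p = 0.237) or without any 1 of the CPD arrays (0.058 to 0.063). The UV effect differed for 1817 6-mers, 115 tetranucleotides, 63111 probes and 8 of the 12 lists, although limma called 0 probes with quantile normalization and camera 0 lists with an estimated correlation. Among isolated printed-strand steps it differed by 0.47 for TT and -1.06 for TC. Relative to the array medians the 6-mers farthest toward CPD were AAAAAC (1.96), AAAACC (1.79), GTTAAC (1.78), GTTATA (1.74), GTAAAC (1.71), AAAACG (1.70), AAATTT (1.69), AACGTT (1.68), GTTACA (1.66) and GGTTAC (1.62). Those farthest toward 6-4PP were GATCAC (-1.75), GGATCC (-1.74), GATCGA (-1.70), CGATCG (-1.69), CTGATC (-1.68), CCGATC (-1.67), GGATCA (-1.62), GAGCTC (-1.61), ATCATC (-1.60) and CTCATC (-1.60). Of the factor cores, 11 differed: TATAAA (1.26), TAATTA (0.79), AGATAA (0.34), TGTGGT (0.29), TGACGT (0.25), TTCCGG (0.23), TTAGGG (0.074), CATGTC (-0.18), GGGCGG (-0.35), GGGACT (-0.50) and TGACTC (-0.93).

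Spots outside the comparisons also stained more after UV, on both UV arrays above both non-UV arrays. Their median intensity rose with the CPD and the 6-4PP antibody, in that order, 7.78-fold and 17.6-fold at DCP controls, 3.32-fold and 8.37-fold at E1A controls, and 6.30-fold and 20.9-fold at ETG controls. At bright corner spots it rose at least 56.1-fold, with all 28 CPD readings after UV at the scanner ceiling, and 14.95-fold, at dark corner spots 4.48-fold and 12.9-fold, at negative controls 4.25-fold and 11.8-fold, and at spike-in controls 11.5-fold and 27.3-fold. Unnamed spots rose 1.11-fold and 1.27-fold. The 9 printed sequences with another 3′ end, which entered the probe tests but are described in no comparison, rose 21.8-fold and at least 32.5-fold, with 233 of 400 6-4PP readings after UV at the ceiling.

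Single TT and TC steps gave more signal on the printed strand than on its complement. If the complement strand were present on the same share of molecules at every probe, TT and TC might lose the same fraction. With the 6-4PP antibody in matched flanking bases, all with A before the step, the lowest complement-to-printed ratio of TC was 1.38 times the highest of TT. Equal ratios would follow only if lacking the complement changed the staining of printed TT and TC alike. That was not tested, so the ratios cannot decide this cause. Another possible cause is that the antibody reached steps near the printed 5′ end less well on both strands. Lone TT steps lay at nearly the same positions on both strands (median 11 printed, 10 complement), and slopes on position were at most 0.056 log2 units per base. Such an effect could hardly set the strands apart. With position and flanking bases modelled, printed TT stayed at least 0.88 log2 units above complement TT on each UV array, a result these positions fixed largely in advance. It stays open whether the complement strand stops short of the printed 5′ end, because the slope of complement TT signal on position exceeded that of printed TT by at least 0.020 log2 units per base on every UV array, under 2 standard errors on 2 of the 4 arrays (SE 0.0119 at the smallest excess). No biological explanation was tested.

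Same-numbered arrays of the 2 antibodies deviated together from their groups, within the UV arrays and within the non-UV arrays. Among spots repeating 1 sequence the replicate differences of the antibodies correlated by 0.733 or more, which argues against a deviation that belongs to the sequences. The correlation was still 0.699 or more once the mean of the neighbouring spots was taken out, which argues against a smooth trend over the slide. These are Pearson values. Over all spots Spearman rho was lower, 0.394 (non-UV) and 0.425 (UV), beside Pearson r of 0.766 and 0.712. Spots with large differences thus weigh heavily in r. The value of 0.733 is consistent with the same spots of 1 physical array being read with both antibodies, which the labels do not state; between UV and non-UV arrays the correlation was 0.00338 or less. No biological explanation was tested.

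Probes without a dipyrimidine step brightened with UV, 1.42-fold with each antibody (a rise of 476 with CPD and of 581 with 6-4PP). A rise of the whole surface was tested at unnamed spots, whose nature the labels do not give and which rose by at most 27.4 percent as much; this argues against an equal rise at every spot as the whole cause. Dark corner spots and negative controls, whose sequences are not listed, rose more than the probes without a step, and a rise limited to some kinds of spot stays open. Light from bright neighbours was examined at the spots in the lowest 10 percent of neighbour brightness. In unadjusted intensity these spots kept 79.0 percent of the rise with CPD and 63.4 percent with 6-4PP. How bright their neighbours still were after UV was not examined, so these shares cannot decide whether such light was the cause. Damage at bases other than adjacent pyrimidines was not tested, and neither was antibody binding to undamaged DNA after UV.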

How the results depend on the processing

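The shared-array block, the restriction to the common 3′ end, the restriction to the first 24 bases, the crossed numbers, and every setting of the isolated steps were chosen only after the data had been seen; the other settings were chosen before. In all, 188 results were recomputed, giving 2992 values. Of the values that answer a comparison, 253 under other settings and 119 with 1 array left out were classed as unchanged. An effect was classed so when it kept its direction and its side of the threshold. A count was classed so when it stayed within 1.5-fold, whatever the directions. An array level was classed so when it shifted by less than the replicate SD. Counts of 6-mers per antibody were thus classed as unchanged without centring, although every 6-mer then rose. Of the values of named sequences, 1669 and 820 kept their direction and side of the threshold. With 1 array left out, a lone array is assumed to vary like the other groups. For each antibody only its own arrays were left out for these values, and for the difference every array in turn. Counts then ranged from 2026 to 2041 (CPD), 1964 to 1988 (6-4PP) and 1738 to 1903 (difference) for 6-mers, from 88591 to 91178, 84849 to 90221 and 49795 to 62566 for probes, and from 121 to 123, 120 to 122 and 114 to 121 for tetranucleotides. The array levels ranged from 1.18 to 1.42 and from 1.90 to 2.20. The CPD effect of TC ranged from 0.0130 to 0.0186 and was not past the threshold without non-UV CPD array 2 (0.0130). Among named sequences and isolated classes, 15 values with 1 array left out and 12 under other settings were no longer past the threshold, 5 and 5 were newly past it, and 60 changed sign. Keeping flagged spots was not run, since none was flagged, nor was the slide as a block, since the files give no slide. Signal over background is a limit: the background was not subtracted, and non-UV probe values carry little beyond noise.

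Numbers of past-threshold sequences, for CPD, 6-4PP and the difference in this order, changed with the number tested: 495, 481 and 464 of 512 5-mers; 8005, 7679 and 6783 of 8192 7-mers; and, on the printed strand alone, 3906, 3845 and 3493 of 4096 6-mers and 236, 237 and 224 of 256 tetranucleotides. With the dimmest 25 percent of probes left out, 59547 of 91571 probes were called for 6-4PP. Quantile normalization called 8435, 6561 and 0 probes with limma (15640 at an unadjusted p under 0.05 for the last), and no centring called 42054 probes for the difference; the cause was not tested. An estimated correlation left 0, 0 and 0 lists called. Means over probes put the array level at 1.93 and 2.32; the cause was not tested.

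The small step effects depended on the model, and the cause was not tested. CPD effects of TC and CT were -0.071 and -0.019 with dim probes left out and -0.019 and -0.014 for the complement strand's own terms, and CT was -1.99 percent on a linear scale. CPD effects of CC were 0.0060 with G and C content added, 0.00035 for the printed strand's own term and 0.042 for isolated steps. The 6-4PP effect of CC was 0.0023 for the complement strand. The 6-4PP order of TC over TT turned for isolated steps pooled over both strands (0.73 for TC and 0.83 for TT). Isolated steps gave differences of 0.037 for CT and -0.038 for CC.

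Without centring, sequences below the array median with 1 antibody took the sign of its overall rise, by construction. For CPD these were TGTGGT (1.36), ACGCCC (0.77), TGACGT (1.16), GGGACT (1.39), CACGTG (0.75), CATGTC (1.00), CCCACG (0.76), GGGCGG (0.82), CGTACG (0.77), CGTGCC (0.77), GACACC (0.77), GACGTC (0.77), TGACTC (1.29) and GGCGCC (0.73), and GCTG (1.07), CCTG (1.05), CCCG (1.04), CCTC (1.06) and GCCC (1.05). For 6-4PP they were AACGTA (1.07), ACACGT (0.98), ACATGT (1.06), TGTGGT (1.70), ACCGTA (1.20), ACGCGT (0.99), ACGTAC (1.20), ACGTAT (1.18), TGACGT (1.54), CACGTG (1.32), CATGTC (1.81), GGGCGG (1.80), TTCCGG (2.16) and GACGTA (1.15), and GTTT (1.85), ACCC (1.92), ACCG (1.84), ACTG (1.93) and GCTG (1.88). For the difference, the sign of the larger overall 6-4PP rise was taken by TGTGGT (-0.34), TGACGT (-0.38), AGATAA (-0.29), CACGTG (-0.57), TTAGGG (-0.56) and TTCCGG (-0.40).

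Other reversals of named 6-mers were few, and the cause was not tested. With dim probes left out, CPD values were 0.10 for TGTGGT, 0.0011 for TGACGT and -0.30 for TTCCGG, the 6-4PP value was -0.32 for TATAAA, and the difference was -0.17 for CACGTG and -0.029 for TTAGGG. With quantile normalization the CPD value was -0.090 for TTCCGG, the 6-4PP value -0.076 for TATAAA, and the difference -0.13 for CACGTG and -0.18 for TTAGGG. Means for medians gave 0.030 for TGACTC (CPD), -0.056 for TATAAA (6-4PP) and 0.14 for CATGTC (difference). The printed strand alone gave -0.34 for TTCCGG (CPD), -0.12 for GGGACT and -0.21 for TATAAA (6-4PP).

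Replicate numbers are shared by the groups. Over 6-mers, deviations of same-numbered UV and non-UV arrays correlated by -0.41 (CPD) and -0.10 (6-4PP). Those of the 2 antibodies correlated by 0.35 within the non-UV and by -0.014 within the UV condition. The 6-mer values cannot settle pairing, because they miss the shared deviation of UV arrays that probes show. At probe level, same-numbered UV and non-UV arrays shared no deviation (0.00079 for CPD and -0.0032 for 6-4PP). Over probes, same-numbered arrays of the 2 antibodies did deviate together within the non-UV (0.765) and the UV condition (0.707). With the replicate block, 2037, 1996 and 1802 6-mers, 98778, 94708 and 65243 probes and 122, 123 and 115 tetranucleotides were called. With the numbers crossed between UV and non-UV arrays the block called 2041, 2005 and 1817 6-mers and 98846, 94673 and 65191 probes. Arrays of the same UV condition and number as a random block gave 2042, 2003 and 1824 6-mers and 97559, 93367 and 76854 probes.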

Other observations

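The values on triplets and designed probe families were chosen for description only after the data had been seen. Lone pyrimidine triplets on the printed strand split by the place of the cytosine. With the 6-4PP antibody after UV, CTT gave 8744 ± 61.5 (SD, n = 2) above probes without a step, TTC 6711 ± 25.7, CTC 4716 ± 14.7, TCC 3718 ± 45.7, TCT 1116 ± 199 and CCC 325 ± 10.5. With the CPD antibody TTC gave 5744 ± 171 and CTT 4362 ± 486, while CTC gave 297 ± 20.8 and TCC 126 ± 1.14. On the printed strand TTC was the 1 triplet of 8 whose UV effect did not pass the limma test for a difference between antibodies (0.06, adjusted p = 0.0608), while on the complement strand it leaned to 6-4PP (-0.17, adjusted p = 0.00575). These log2 tests depend on the signal over background of each antibody, so a missing call does not show equal lesion signal. TCC (-1.41, adjusted p = 1.40e-10) and CTC (-1.52, adjusted p = 1.40e-10) leaned most to 6-4PP, CTT (-0.55), TCT (-0.36), CCT (-0.34) and CCC (-0.20) less, and TTT (1.05, adjusted p = 2.28e-07) leaned to CPD.

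The array also carries families of probes named for DNA-binding factors, and their order after UV differed between the antibodies. The 194 GATA sequences gave 5227 ± 29.2 (SD, n = 2) above probes without a step with the 6-4PP antibody and 452 ± 43.8 with the CPD antibody, with a mean of 1.97 TC and 0.325 TT steps per probe. The 194 RUNX sequences, with a mean of 1.15 TT and 0.381 TC steps, gave 1073 ± 7.04 and 1994 ± 205. The 194 E2F1 sequences gave 348 ± 52.6 and 82.3 ± 5.68, and the 482 Myc sequences 332 ± 32.2 and 100.02 ± 3.17. The 988 CTCF sequences gave 3561 ± 57.1 and 770 ± 119, and the 1382 ETS1 sequences 3757 ± 65.05 and 890 ± 64.2. Without UV the means of these 6 families lay between 5.09 and 16.3 above probes without a step with the CPD antibody, and between -20.0 and 63.1 with the 6-4PP antibody. No test was made between families.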
